A study of Mus musculus with 60 samples.

How the data were processed

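RNA was measured in the prefrontal cortex of mice on postnatal day 25. The mice were wild type (WT) or heterozygous (Het) for the C456Y allele of Grin2b, which encodes the GluN2B subunit of the NMDA-type glutamate receptor. From postnatal day 3 to 24 the pups received vehicle, fluoxetine or lithium through the milk of their mothers. Fluoxetine is a selective serotonin reuptake inhibitor, and lithium is a mood stabiliser known to inhibit glycogen synthase kinase 3. With 2 genotypes, 3 treatments and 2 sexes there were 12 groups of 5 libraries, 60 in all. The labels number the replicates but do not say whether each is a separate animal or litter. The drug came through the mother, so littermates would share it. The p-values therefore measure the spread between these samples.

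Libraries were made with a stranded mRNA kit, per the labels' protocols. Salmon 0.11.2, DESeq2 1.19.11, R 3.6.0 and the mouse genome build GRCm38 are named in the submitters' processing notes, without their roles or order. Whether counting used the strand is not given in the sources used here. The deposited values are a signal per gene that is never negative, and are called normalised read counts here. Within each column they were whole multiples of a fixed step, so the authors divided gene read counts by 1 size factor per library. Dividing by the step gave back whole reads, within 0.001 of a whole number, for 100% of the values. The recovered totals were 23901635 to 37769417 reads per library.  Of the 18088 genes in the table, 17801 to 18038 had reads in a library and 5 had none in any. The top gene, the mitochondrial mt-Co1, took 1.65% to 3.8% of the reads. Symbols and GRCm38 coordinates came from GENCODE release M21, in which 18077 of the gene identifiers were found.

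The test was limma 3.58.1 in R 4.3.3 on log2(value + 1), with trend and robust settings, for the 17810 genes with a value of at least 10 in at least 5 libraries. A model with 12 group means and 48 residual degrees of freedom was fitted to all libraries, and 24 contrasts were taken from it: 7 averaged over the sexes, 10 within a sex and 7 interactions. Genes are called at a Benjamini-Hochberg adjusted p below 0.05 within a contrast. Fold changes are on the log2(value + 1) scale, which understates the change of low genes. SE is the standard error from that model, and means of normalised read counts are given ± SD. In 5 contrasts, 40 gene lists were tested with camera at a preset correlation of 0.01, with adjustment over the lists, and again with an estimated correlation. The lists held pathways, receptor families and markers of the cell types that a cortical dissection can hold. For each list the members were also adjusted over the list alone.

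These choices were made before the data were examined, as were the rules for the named genes. Named genes passed an adjusted p of 0.05 and had a symbol that was neither a predicted-gene number nor a RIKEN clone name, and was not Xist or Y-linked. In each contrast averaged over the sexes, these were the 10 with the smallest p in each direction, and in each called list the 4 called members with the smallest p in its direction. Where fewer than 5 genes pass, the 5 with the smallest p are named. In contrasts within a sex and interactions they were the 3 with the smallest p in each direction. Grin2b, Grin1 and Grin2a are always given. A few genes that the rule selects are not reported here, and counts include them. Any other gene is said to have been chosen after its values were seen. The design allowed for counts or normalised values, and as the values are normalised the count test was not the main one.

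The alternatives planned in advance were factors from the trimmed mean of M values, no filter on low values, a pseudocount of 5, a fit to the groups compared alone, the replicate number as a block, fry and an estimated correlation for the lists, and each library left out in turn. Further ones were chosen after seeing the data. The first was the quasi-likelihood test of edgeR 4.0.16 on the recovered reads (17776 genes). The second was a GC correction, which subtracted from each library a loess curve (span 0.3) of its deviations on the GC content of each gene's longest transcript. GC content was known for 99.94% of the genes. The third left out the 3 libraries with the largest residuals: WT lithium male replicate 5, WT lithium female replicate 5 and WT vehicle female replicate 2. The last were terms for libraries low in a group of pseudogenes, described in the results. The first set tried held the 11 libraries with no read of Rps6-ps4, by a test written before its result was seen. After that result was seen, a second set held the 10 libraries below the widest gap in the mean level of 16 pseudogenes, and its term is called the library term.

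The model was tested on simulated reads for the real genes, with 200 genes changed in each of 5 simulations. For the genotype contrast in vehicle it recovered 74.1% of 1.5-fold and 92% of 2-fold changes, and 5.71% of its calls were false. Within females the shares were 68%, 82.3% and 7.27%, and for the interaction of genotype with lithium 65.2%, 84.1% and 6.43%. A list lowered by design was called in 100% of the simulations, and 0.513% of the other lists were called. On the real libraries, however, other splits called a median of 11 to 13 of the 40 lists, so on these data the number of lists called by camera is a weak guide. A GC tilt with no changed gene gave 4700 calls on average in the genotype contrast in fluoxetine, and 0.2 after GC correction. The tilt was planted on the same GC values that the correction uses, so this does not show how well a real bias is removed. The sex genes matched the labels in all 60 libraries: Xist was 17023.1 to 30646.9 in females and 0 to 10.2 in males, and Ddx3y 0 to 8 and 956 to 2736.8. No pair of libraries in a group differed by as little as sampling noise (chi-square per gene 4.62 at the lowest). For each contrast, 100 splits of the libraries into groups of the same size were drawn to count how often another split calls as many genes.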

Results

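The study measured RNA in the prefrontal cortex on postnatal day 25, in 60 libraries, after 3 weeks of vehicle, fluoxetine or lithium. Het mice carried the C456Y missense allele of Grin2b, and WT mice did not. Each of the 12 groups held 5 libraries, so a contrast averaged over the sexes compared 10 libraries with 10. The comparisons cover genotype, each drug in each genotype, and whether the drugs move the genotype difference.

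Grin2b itself lies on chromosome 6 at 135713233 to 136173511. As the allele changes an amino acid, its RNA level does not check the genotype. In vehicle the normalised read count of Grin2b was 18491.5 ± 1958.7 in Het and 17329.8 ± 1493.8 in WT mice (n = 10 each). The log2 fold of 0.091 (SE 0.064) was within the spread, with an adjusted p of 0.709, and 8 of 10 Het libraries lay above the WT mean of their sex. The other NMDA receptor subunits Grin1 and Grin2a were at log2 folds of 0.024 (adjusted p = 0.968) and 0.085 (adjusted p = 0.789).

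In vehicle, Het mice had more of the long noncoding RNAs Meg3 and Miat, of the potassium channel gene Kcnk9 and of the microRNA host gene Mir124a-1hg. Meg3, the maternally expressed RNA of the imprinted Dlk1-Dio3 cluster (chromosome 12, 109541001 to 109571726), was at 155874.6 ± 7587 in Het and 123578 ± 11077.9 in WT mice. This is a log2 fold of 0.34 (SE 0.044, adjusted p = 4.94e-06), and all 10 Het libraries lay above the WT mean of their sex. Miat rose by a log2 fold of 0.39 (SE 0.056, adjusted p = 4.15e-05), Kcnk9 by 0.29 (SE 0.046, adjusted p = 0.000255) and Mir124a-1hg by 0.28 (SE 0.049, adjusted p = 0.00119), each in 10 of 10 libraries. Spaca6 (0.33), Ankrd27 (0.22), Spag5 (0.41), Rbm33 (0.16), C78859 (0.25) and Abcc5 (0.17) also rose. Among the genes that fell, the mitochondrial transcript mt-Co2 had a log2 fold of -1 (SE 0.212, adjusted p = 0.017), with a mean of 43028.1 ± 7926.6 in Het and 90406.4 ± 32086.8 in WT mice. Nuclear copies of mitochondrial genes could share its reads, so its value is uncertain. The myokine precursor gene Fndc5 (-0.22), the transcription factor genes Tfap2d (-1.29) and Mycl (-0.28), Ephx1 (-0.27), Nell1 (-0.28), Derl1 (-0.12), Inf2 (-0.25) and Itm2b (-0.14) fell as well, as did Olfr316 (-0.52), whose reads other olfactory receptor genes could share. Under fluoxetine Meg3 ran the other way in females, from 115614.6 to 137495.4 in Het and from 141364.5 to 176143.8 in WT libraries. Its ranges in males overlapped, as did those of both sexes under lithium.

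In vehicle limma called 105 genes, 92 higher and 13 lower in Het mice, and edgeR called 90. With 1 library left out the 10 named genes that rose kept their calls in each of 20 fits. The 10 that fell did not: mt-Co2 kept its call in 18 fits, Fndc5 in 15, Tfap2d in 11, Nell1 in 10, Derl1 and Ephx1 in 9, Mycl and Olfr316 in 8, Itm2b in 5 and Inf2 in 3. The count was 210 after GC correction, 343 without the 3 libraries with the largest residuals, 105 with the library term and 47 with the 4 groups fitted alone. Leaving out a Het vehicle library gave 50 calls (female replicate 1), 69 (female 2), 22 (female 3), 49 (male 1), 36 (male 2), 22 (male 3) or 58 (male 4). Leaving out a WT vehicle library gave 26 (female 1), 17 (female 4), 22 (female 5), 26 (male 1), 55 (male 2) or 39 (male 3).

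Of the 40 gene lists, camera called 11 between Het and WT mice in vehicle. Members of the lists for meningeal fibroblasts (median log2 fold -0.24, 24 measured, adjusted p = 5.76e-10), oligodendrocytes and myelin (-0.17, 34 measured, adjusted p = 1.5e-06), pericytes and smooth muscle (19 measured, adjusted p = 0.000143) and immature neurons of the olfactory bulb (-0.41, 21 measured, adjusted p = 0.000165) ranked low in Het mice. So did those for astrocytes (28 measured, adjusted p = 0.000993), extracellular matrix (32, adjusted p = 0.00117), oligodendrocyte precursors (18, adjusted p = 0.00155), cholesterol synthesis (25, adjusted p = 0.00156) and microglia (28, adjusted p = 0.0377). Lists of chromatin regulators (48 measured, adjusted p = 0.0156) and nuclear-encoded oxidative phosphorylation (76, adjusted p = 0.0329) ranked high. No member of the 11 lists was called by limma over all genes, where 1736 genes passed an unadjusted p of 0.05 in total. Adjusted over the list alone, 2 chromatin regulators were higher, 2 pericyte genes lower, and 1 immature neuron gene was higher and 1 lower. With an estimated correlation none of the 11 calls held, at adjusted p = 0.539 to 0.783. The calls of the last 3 lists given, microglia, chromatin and oxidative phosphorylation, held in 10, 17 and 11 of the 20 fits with 1 library left out. The library term ended those for oxidative phosphorylation (adjusted p = 0.165) and chromatin (adjusted p = 0.06).

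**Figure D1:**
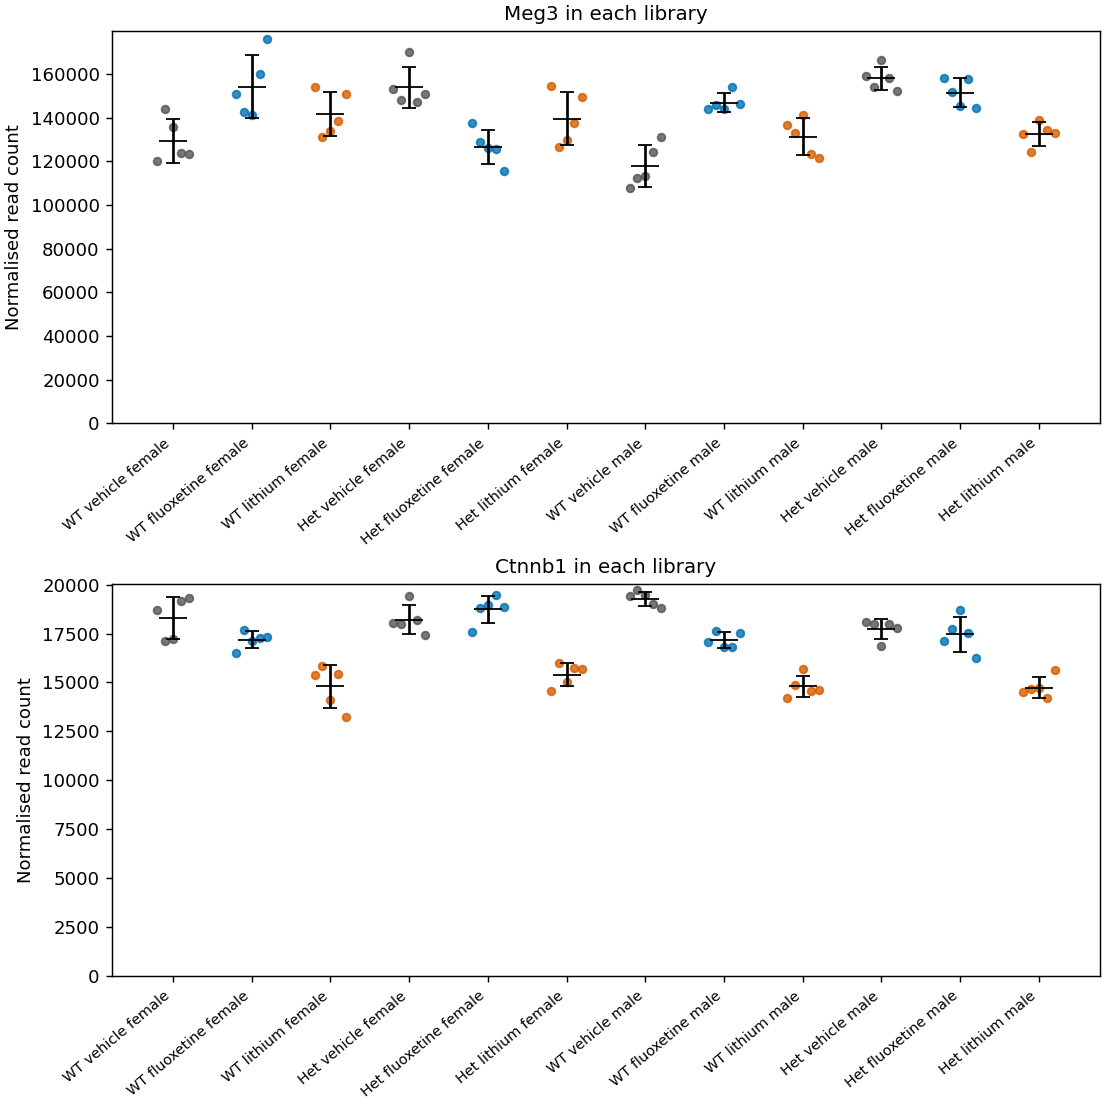
Normalised read counts of Meg3 and of Ctnnb1 in each of the 60 libraries by group (points), with the mean and SD of 5 libraries (black). In vehicle Meg3 was higher in Het libraries (155874.6 against 123578 on average), and Ctnnb1 was lower in lithium than in vehicle libraries in both genotypes.

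Fluoxetine in WT mice lowered genes of cholesterol synthesis and activity-regulated transcription factors and raised genes known to respond to glucocorticoids. Of 25 measured genes of cholesterol synthesis 18 fell, 0 rose and 7 were not called. Among them were the isomerase gene Idi1 (log2 fold -0.41, SE 0.068), the squalene epoxidase gene Sqle (-0.24, SE 0.04), the sterol carrier gene Stard4 (-0.31, SE 0.051) and Sc5d (-0.23, SE 0.044), each lower in 10 of 10 libraries. Of 32 immediate-early genes 11 fell and none rose, with Egr2 at -1.16 (SE 0.188), Nr4a3 at -0.88 (SE 0.114), Fosl2 at -0.77 (SE 0.128) and Egr1 at -0.69 (SE 0.116). Egr1 went from 7324.5 ± 1218.4 in vehicle to 4543.9 ± 903.2 in fluoxetine. Of 24 glucocorticoid-responsive genes 11 rose and none fell, including Fkbp5, the co-chaperone of the glucocorticoid receptor (0.43, SE 0.08), Plin4 (1.04, SE 0.181), Hif3a (0.71, SE 0.093) and Map3k6 (0.65, SE 0.098).

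The remaining calls in WT fluoxetine were spread over other functions. Rbm33 (0.27), the phospholipid flippase gene Atp10d (0.71), Tmem82 (from 23.6 ± 5.4 to 47.8 ± 7.3), Spaca6 (0.43), the kinase gene Hunk (0.46), Oacyl (1.02), Greb1l (0.52), Acr (1.04) and Ankrd16 (0.40) rose. Nol4l fell by 0.34 on the log2 scale (SE 0.034, adjusted p = 6.48e-10), from 2383.9 ± 77.5 to 1880 ± 72.6. Fam53b (-0.60), the transcriptional corepressor genes Bcor (-0.41) and Cbfa2t3 (-0.64), Banp (-0.53), Zhx2 (-0.61), Map3k19 (-0.67), Cdc42ep4 (-0.40) and Efnb1 (-0.42) also fell, each in 10 of 10 libraries. Grin2b was at 0.17 (adjusted p = 0.0976) and at an adjusted p of 0.029 after GC correction. Grin2a rose by 0.23 (adjusted p = 0.0394), a call kept in 7 of 20 fits with 1 library left out and not made by edgeR (adjusted p = 0.0506). In all, 1502 genes were called, 775 higher and 727 lower, with 1500 by edgeR and 1559 with the library term.

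By camera, cholesterol synthesis was called lower at an adjusted p of 5.55e-17, and its call held at adjusted p = 0.0051 with an estimated correlation. Adjusted over the list alone, 21 of its genes were lower. The immediate-early genes (adjusted p = 3.43e-11), the glucocorticoid-responsive genes (adjusted p = 2.4e-09) and the list for heat shock and the unfolded protein response (adjusted p = 3.53e-07) were called as well. With an estimated correlation these 3 were at adjusted p = 0.244, 0.247 and 0.247, so the calls did not hold. Adjusted over the list alone, 17 immediate-early genes were lower, 13 glucocorticoid-responsive genes higher and 8 of 30 heat shock genes lower. Over all genes 4 of those 30 fell, namely Xbp1 (-0.25), Atf4 (-0.14), Dnajb1 (-0.16) and Dnajc3 (-0.14), of which the last pair kept their calls in 14 and 13 of 20 fits with 1 library left out. Of 28 Wnt pathway genes 6 fell (adjusted p = 0.00396, and adjusted p = 0.247 with an estimated correlation), including Lef1 (-0.52), Tcf7l2 (-0.64), Ccnd2 (-0.24) and Ctnnb1, which encodes beta-catenin (-0.13, SE 0.031).

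Some markers of vessels fell in WT fluoxetine. Of 25 endothelial markers 8 fell, with Cldn5 at -0.43, Tek at -0.34, Flt1 at -0.37 and Ocln at -0.28 (adjusted p = 1.99e-06 for the list, and adjusted p = 0.362 with an estimated correlation). Adjusted over the list alone 11 were lower. Of 19 pericyte and smooth muscle markers 1 fell, Acta2 (-0.53; adjusted p = 0.00981 for the list, and adjusted p = 0.711 with an estimated correlation). Of 28 interferon genes 1 fell, Irf9 (-0.25; adjusted p = 0.00357, and adjusted p = 0.711 with an estimated correlation). The astrocyte list (3 of 28 lower: Gli3 at -0.31, S1pr1 at -0.20 and Ppp1r3c at -0.20) and the mitochondrially encoded list (1 of 13 lower, mt-Co2 at -0.69) were each at an adjusted p of 0.047, and at adjusted p = 0.962 and 0.944 with an estimated correlation. By camera these last lists were at adjusted p = 0.0682 and 0.119 with the library term. With the replicate number as a block they were at adjusted p = 0.0588 and 0.0561. Their calls held in 8 and 10 of 20 fits with 1 library left out. Ppp1r3c and mt-Co2 kept their own calls in 6 and 11 of those fits.

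**Figure D2:**
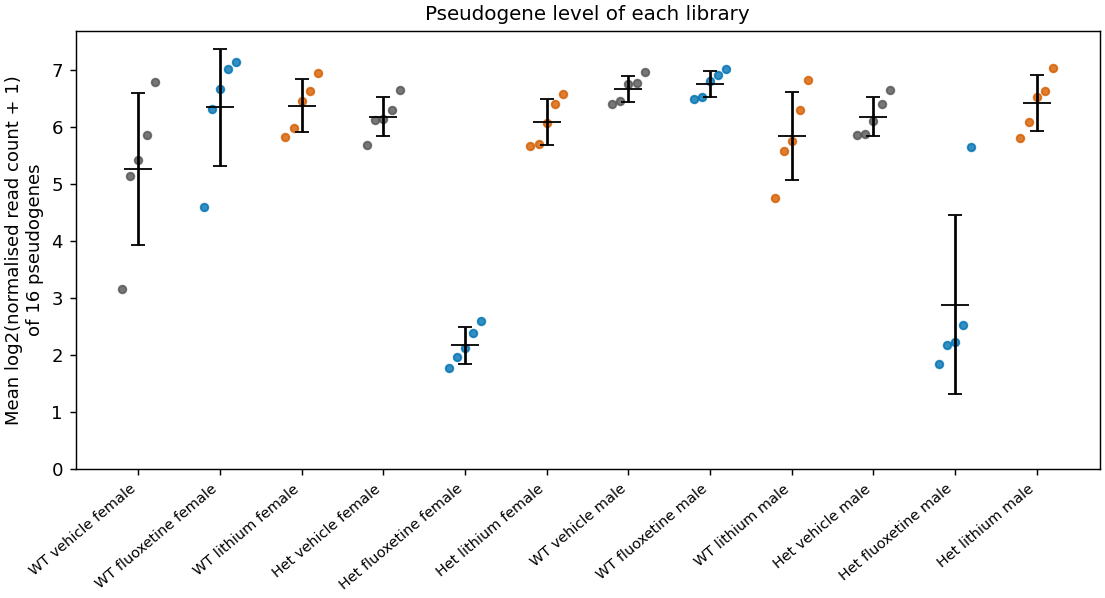
Mean log2(normalised read count + 1) of 16 pseudogenes in each of the 60 libraries by group (points), with the mean and SD of 5 libraries (black). The pseudogenes were chosen as called over 4-fold lower in Het than in WT fluoxetine libraries. Of the Het fluoxetine libraries 9 lie at 2.6 or below, Het fluoxetine male replicate 1 at 5.65, and WT vehicle female replicate 2 at 3.15.

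The libraries of Het mice given fluoxetine stood apart from the rest in ways that bear on the counts for fluoxetine in Het mice and for genotype in fluoxetine. Of 23 genes called over 4-fold between Het and WT mice in fluoxetine, 16 were annotated pseudogenes, all lower in Het. On the mean log2 level of these 16, 9 of 10 Het fluoxetine libraries lay between 1.78 and 2.6, while Het fluoxetine male replicate 1 was at 5.65. The only other library below 4.6 was WT vehicle female replicate 2, at 3.15. These 10 low libraries were not a group of the design, and a term for them was added to the model after seeing the data (the library term). The set tried first was the 11 libraries with no read of the pseudogene Rps6-ps4, which are the same 10 and WT lithium male replicate 1, whose level was 5.58 (the Rps6-ps4 term). The library term was chosen after the result of that first set was known, so both are given. With either term the effects in Het fluoxetine rest on 1 Het fluoxetine library outside the set and on the 1 or 2 WT libraries inside it. The same Het fluoxetine libraries had a trend with GC content: across 11956 genes the Pearson correlation of a library's log2 deviations with GC content was -0.393 to -0.526 in females and -0.188 (male replicate 1) to -0.466 in males. Outside this group it was -0.795 in WT lithium male replicate 5, -0.603 in WT vehicle female replicate 2, -0.413 in Het lithium male replicate 4, -0.392 in WT lithium female replicate 4, -0.351 in Het lithium female replicate 3, -0.303 in Het vehicle female replicate 2 and -0.212 in WT lithium male replicate 4, and above -0.188 in the other libraries.

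**Figure D3:**
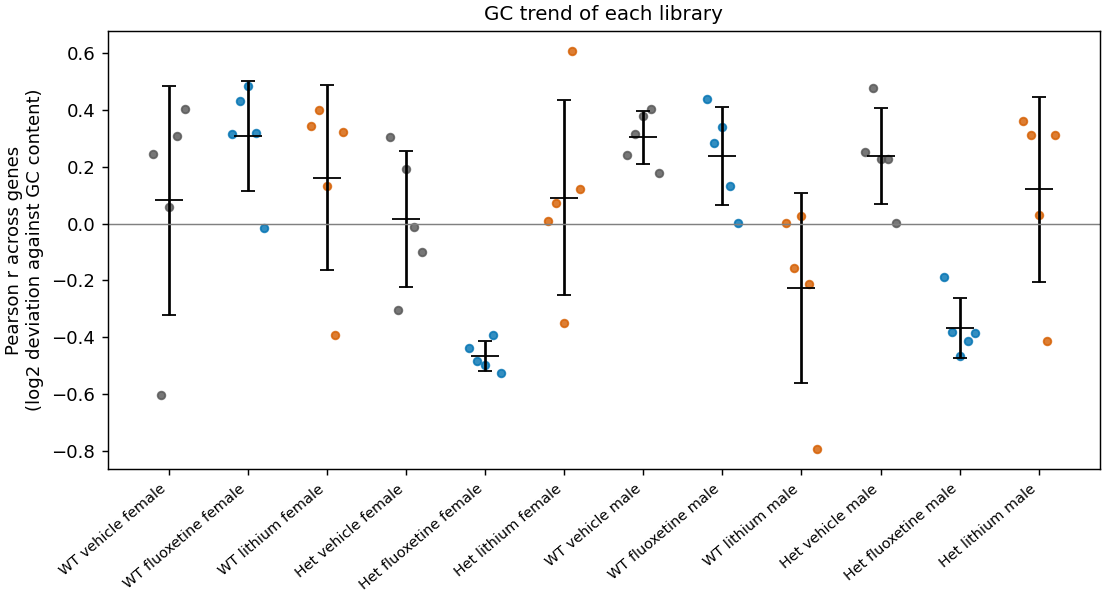
Pearson correlation across genes between the log2 deviation from the mean of all libraries and the GC content of each gene's longest transcript, for each of the 60 libraries by group (points), with the mean and SD of 5 libraries (black). Values in the female Het fluoxetine libraries run from -0.393 to -0.526, and WT lithium male replicate 5 is at -0.795.

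In Het mice given fluoxetine, immediate-early genes and genes of cholesterol synthesis were among the calls, but none of the genes named in this paragraph kept its call with the library term. Across all genes its folds correlated with those of fluoxetine in WT mice at 0.108, inside the simulated range of -0.253 to 0.248 for unchanged groups. Egr1 fell by 1.06 on the log2 scale (SE 0.116, adjusted p = 2.01e-09), from 7684.1 ± 1266.3 to 3738.9 ± 874.6, and Egr2 (-1.39), Fosb (-1.22) and Nr4a3 (-0.86) fell too. Of 32 immediate-early genes 20 fell and none rose. Of 24 glucocorticoid-responsive genes 15 rose and 2 fell, including Fkbp5 (0.53), Plin4 (1.31), Klf9 (0.28) and Hif3a (0.56). Of 25 genes of cholesterol synthesis 15 fell and none rose, among them the regulator gene Srebf2 (-0.28), Mvd (-0.46) and Dhcr7 (-0.27). Htr2a, which encodes the serotonin 2A receptor (chromosome 14, 74640840 to 74709494), rose from 1350 ± 125.1 to 2000.6 ± 190.5 (log2 fold 0.57, SE 0.068, adjusted p = 8.83e-09). Each of these genes moved in its direction in 10 of 10 libraries. Under the library term Egr2 was at -0.85 (adjusted p = 0.393), Fosb at -0.35 (adjusted p = 0.831), Nr4a3 at -0.76 (adjusted p = 0.132), Klf9 at 0.08 (adjusted p = 0.856), Hif3a at 0.44 (adjusted p = 0.38), Srebf2 at -0.12 (adjusted p = 0.591), Mvd at -0.33 (adjusted p = 0.326), Dhcr7 at -0.21 (adjusted p = 0.3) and Plin4 at 1.251 (SE 0.344, against 0.181 without the term; adjusted p = 0.113). Plin4, Nr4a3, Fkbp5, Dhcr7 and Hif3a thus held at least 75% of their folds and lost their calls as the SE rose, while Fosb, Klf9 and Srebf2 were at 50% or less. With the Rps6-ps4 term calls ended for Hif3a (0.53, adjusted p = 0.0539) and Fkbp5 (0.45, adjusted p = 0.061), whose folds changed little, and for Egr2 (-0.89, adjusted p = 0.109), Fosb (-0.54, adjusted p = 0.32) and Klf9 (0.15, adjusted p = 0.286), whose folds fell more, and the others kept theirs.

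The other leading genes included Zc3h6 (0.70), Atp10d (0.80), the neurotrophin receptor gene Ntrk3 (0.33), Zfp810 (0.50), Ankrd49 (0.49), Zfp941 (0.45), the DNA repair gene Brca2 (0.76), the matrix glycoprotein gene Tnr (0.32) and the histone methyltransferase gene Setd2 (0.27), which rose. Fam129b (-0.68), Fam53b (-0.78), Nol4l (-0.37), the death receptor gene Tnfrsf25 (-1.31), Gse1 (-0.70), Ahdc1 (-0.85), the noncoding RNA Mirg of the Meg3 cluster (-0.56), Cbfa2t3 (-0.94) and Serinc2 (-1.11) fell. So did Rpl31-ps8 (-0.71), a ribosomal protein pseudogene whose reads its parent gene could share. Grin2b rose by 0.32 (SE 0.064, adjusted p = 0.000105) and Grin2a by 0.41 (SE 0.075, adjusted p = 3.27e-05), and Grin1 was at -0.15 (adjusted p = 0.107). With the library term they were at 0.26 (SE 0.121, adjusted p = 0.506), 0.14 (SE 0.134, adjusted p = 0.851) and 0.08 (SE 0.139, adjusted p = 0.936), so Grin2b held most of its fold and Grin2a did not. With the Rps6-ps4 term Grin2b was at 0.273 (adjusted p = 0.176) and Grin2a at 0.216 (adjusted p = 0.347). In females Grin2b ran from 23227.3 to 28378.1 in fluoxetine and from 14751.3 to 20458.3 in vehicle, while in males the ranges overlapped. No gene was called for the interaction of sex with fluoxetine in Het mice.

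Fluoxetine in Het mice gave 6952 calls, 3407 higher and 3545 lower. After GC correction there were 3868, of which 2784 were among the first calls in the same direction, with the Rps6-ps4 term 332, and with the library term 49, of which 38 were. The median log2 fold of the 6952 calls was 0.227 (median SE 0.0583), 0.157 with the Rps6-ps4 term (SE 0.0947) and 0.0811 with the library term (SE 0.106). Of the 50 called genes that the naming rule selects 29 kept their calls with the Rps6-ps4 term, Egr1 and Htr2a among them, and 10 with the library term: Zc3h6 (0.57, SE 0.13), Atp10d (0.68, SE 0.159), Setd2 (0.27, SE 0.066), Fam53b (-0.79, SE 0.131), Nol4l (-0.34, SE 0.064), Tnfrsf25 (-1.08, SE 0.224), Ahdc1 (-0.72, SE 0.147), Mirg (-0.47, SE 0.099), Cbfa2t3 (-0.82, SE 0.168) and Serinc2 (-1.11, SE 0.203). Of the 40 that lost their calls with the library term 9 held at least 75% of their fold and 16 held 50% or less. Egr1 was then at -0.70 (SE 0.212, adjusted p = 0.174), Fkbp5 at 0.44 (SE 0.151, adjusted p = 0.281) and Htr2a at 0.38 (SE 0.125, adjusted p = 0.253).

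Camera called 7 lists in Het fluoxetine, and with an estimated correlation none of the 7 held, at adjusted p = 0.456 to 0.665. The immediate-early list was lower (adjusted p = 9.13e-08, 21 genes lower over the list alone), as was cholesterol synthesis (adjusted p = 1.96e-06, 15 lower over the list alone, 22 lower after GC correction), and the glucocorticoid-responsive list was higher (adjusted p = 0.000169, 16 higher and 2 lower over the list alone). Of 78 cytosolic ribosomal protein genes 60 fell and 2 rose (adjusted p = 1.77e-17, 62 lower over the list alone), with Rpl28 (-0.38), Rps16 (-0.36), Rps21 (-0.40) and Rpl38 (-0.48) in the lead. Processed pseudogenes are known for these genes and could share their reads. Of 76 nuclear-encoded genes of oxidative phosphorylation 49 fell and 3 rose (adjusted p = 2.67e-11, 50 lower over the list alone), including Atp5e (-0.42), Atp5g1 (-0.26), Ndufa2 (-0.47) and Ndufv3 (-0.24). Of 20 genes of GABA-A receptors and GABA synthesis 14 rose and 3 fell (adjusted p = 0.000778), with Gabrb2 (0.34) and Gabra3 (0.24) among those that rose. After GC correction 7 rose. Of 25 endothelial markers 13 fell (adjusted p = 0.000307, 14 over the list alone), with Cldn5 (-0.62), Pltp (-0.38), Eng (-0.44) and Vwf (-0.59). With the library term the GABA list was at adjusted p = 0.14 and the other lists kept their direction: cholesterol synthesis at adjusted p = 2.81e-11, ribosomal proteins and oxidative phosphorylation at 1.29e-05 each, immediate-early genes at 5.25e-05, endothelial markers at 0.000572 and glucocorticoid-responsive genes at 0.00529. These fits used only the preset correlation, and rest on 1 Het fluoxetine library outside the set and 1 WT library inside it. Genes of a list are not independent replicates, so these values do not show that the list calls are free of a batch.

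**Figure D4:**
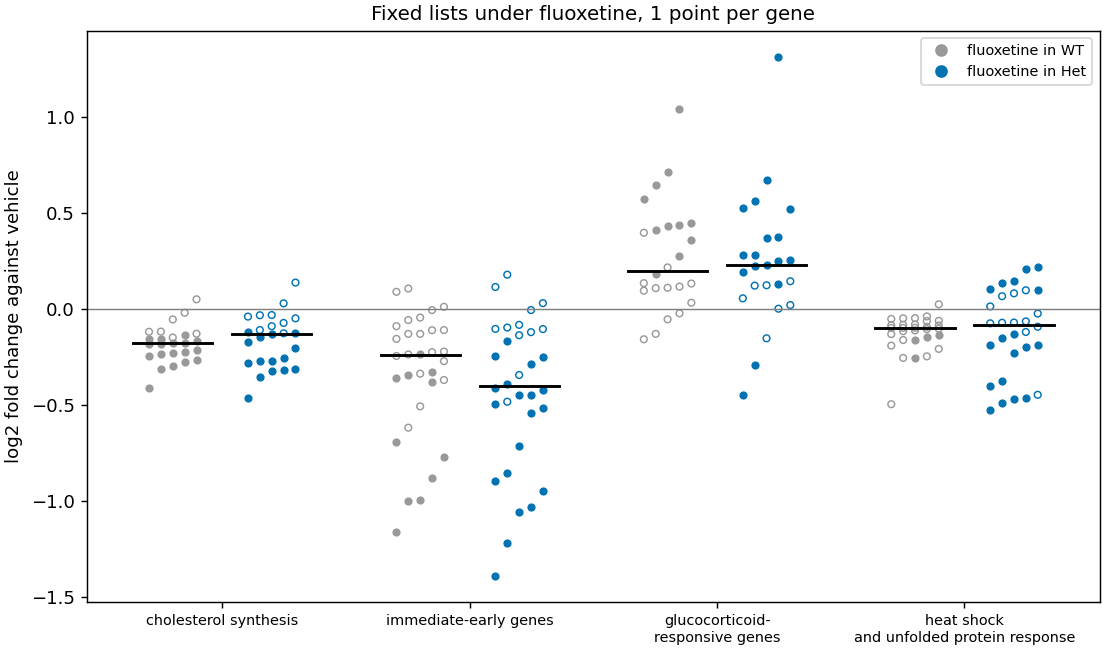
Log2 fold change of fluoxetine against vehicle for each measured gene of 4 lists (points) in WT (grey) and Het (blue) mice. Filled points are genes with an adjusted p below 0.05, and black lines are list medians, which for cholesterol synthesis are -0.18 in WT and -0.13 in Het.

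Between genotypes under fluoxetine 7042 genes were called, 15 with the Rps6-ps4 term and 7 with the library term. The genes Nexmif (0.42), Lrp1b (0.34), Casp8ap2 (0.36), Papolg (0.35), Pura (0.37), Vps13a (0.33), Lin7a (0.36), Ranbp2 (0.32) and Alg10b (0.35) and the cell adhesion gene Ncam2 (0.47) rose. The metalloprotease gene Adam33 (-0.67), the lipid enzyme gene Tecr (-0.23), Ehd1 (-0.35), Zfp865 (-0.37) and the formin gene Inf2 (-0.44) fell, as did Rpl31-ps8 (-0.66), Rps16-ps2 (-0.46) and Rpl37rt (-0.84), whose reads near-identical genes could share. Rps6-ps4 was at 80.5 ± 23.3 in WT and listed at 0 in 9 of 10 Het libraries, and Hist2h2aa2 at 190.3 ± 27.4 in WT and 28.5 ± 60.3 in Het mice. Of the 7042 genes 3497 were higher and 3545 lower. The folds of this contrast correlated with GC content across genes at -0.683. After GC correction 2203 genes were called, 1537 of them first calls in the same direction. Tecr was then at -0.05 (adjusted p = 0.237). The 7 calls with the library term were all higher, and 2 were first calls. The median log2 fold of the 7042 calls was 0.22 (SE 0.0565), 0.15 with the Rps6-ps4 term (SE 0.092) and 0.07 with the library term (SE 0.103). Of the 23 called genes named here 4 kept their calls with the Rps6-ps4 term (Lrp1b, Inf2, Adam33 and Rpl31-ps8) and 0 by limma with the library term. Of the 23 calls lost with the library term, 5 held at least 75% of their fold and ended as the SE rose: Adam33 at -0.62 (SE 0.148, against 0.078 without the term), Inf2 at -0.40 (SE 0.116, against 0.061), Lin7a at 0.32 (SE 0.095, against 0.05), Lrp1b at 0.29 (SE 0.082, against 0.044) and Grin2b at 0.18 (SE 0.121, against 0.064). A further 11 held 50% or less. With the Rps6-ps4 term 10 of the 19 lost calls held at least 75%, and 5 held 50% or less. Grin2b rose by 0.24 (adjusted p = 0.00198), Grin2a by 0.26 (0.00466), and Grin1 fell by 0.27 (0.00361), and after GC correction these were at 0.14, 0.13 and -0.04 (adjusted p = 0.109, 0.167 and 0.635).

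Lithium in WT mice lowered Ctnnb1, the gene for beta-catenin, and most of the listed markers of microglia and vessels. Ctnnb1 (chromosome 9, 120929216 to 120960507) went from 18789.4 ± 908.3 in vehicle to 14800.1 ± 815.8 in lithium, a log2 fold of -0.34 (SE 0.031, adjusted p = 1.47e-11) seen in 10 of 10 libraries. The Wnt target genes Nkd1 (-0.34, SE 0.058) and Lef1 (-0.68, SE 0.121) and the ligand gene Wnt7b (-0.30, SE 0.079) fell with it, among 12 lower and 0 higher of 28 genes of that list. Of 28 microglia markers 21 fell and none rose, including the complement genes C1qc (-0.32) and C1qa (-0.30), the receptor gene Csf1r (-0.32) and Olfml3 (-0.37). Of 25 endothelial markers 17 fell, with Cldn5 (-0.64), Cdh5 (-0.46), Pltp (-0.34) and Tek (-0.37). Of 19 pericyte and smooth muscle markers 14 fell, with Acta2 (-0.70), Vtn (-0.51), Myl9 (-0.50) and Tagln (-0.49).

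Members of other cell type lists fell as well in WT lithium, though none of these list calls held with an estimated correlation. Of 28 astrocyte markers 12 fell, with Ppp1r3c (-0.41), S1pr1 (-0.29), Mlc1 (-0.31) and Gja1 (-0.30). Of 18 oligodendrocyte precursor markers 8 fell and 1 rose, with Gpr17 (-0.55), Sox10 (-0.53), Cspg5 (-0.18) and Lims2 (-0.28) lower. Of 34 oligodendrocyte and myelin markers 9 fell, with Car2 (-0.28), Bcas1 (-0.61), Cryab (-0.37) and Sox10. Of 24 meningeal fibroblast markers 16 fell and 1 rose, with Igf2 (-0.48), Col3a1 (-0.69), Col1a2 (-0.55) and Foxd1 (-0.62) lower, and of 32 extracellular matrix genes 18 fell, with Lama4 (-0.37), Col18a1 (-0.51) and Fbln5 (-0.41). Of 28 interferon genes 8 fell, including Irf9 (-0.28), Gbp2 (-0.43), Ifitm3 (-0.35) and H2-K1 (-0.26).

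By camera these lists were called lower at adjusted p = 4.81e-14 (microglia), 1.35e-11 (endothelial), 5.65e-10 (pericyte), 2.98e-08 (matrix), 2.14e-07 (meningeal), 4.49e-07 (oligodendrocyte), 6.43e-07 (astrocyte), 3.1e-06 (Wnt), 2.91e-05 (precursor) and 4.23e-05 (interferon). With an estimated correlation none held: adjusted p = 0.167 for microglia, endothelium and pericytes, 0.116 for Wnt, 0.24 for precursors, 0.285 for matrix, 0.293 for astrocytes and meninges, 0.441 for interferon and 0.492 for oligodendrocytes. Adjusted over the list alone, 25 microglia, 18 endothelial, 17 pericyte, 18 matrix, 19 meningeal, 17 oligodendrocyte, 14 astrocyte, 13 Wnt, 9 precursor and 9 interferon genes were lower.

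**Figure D5:**
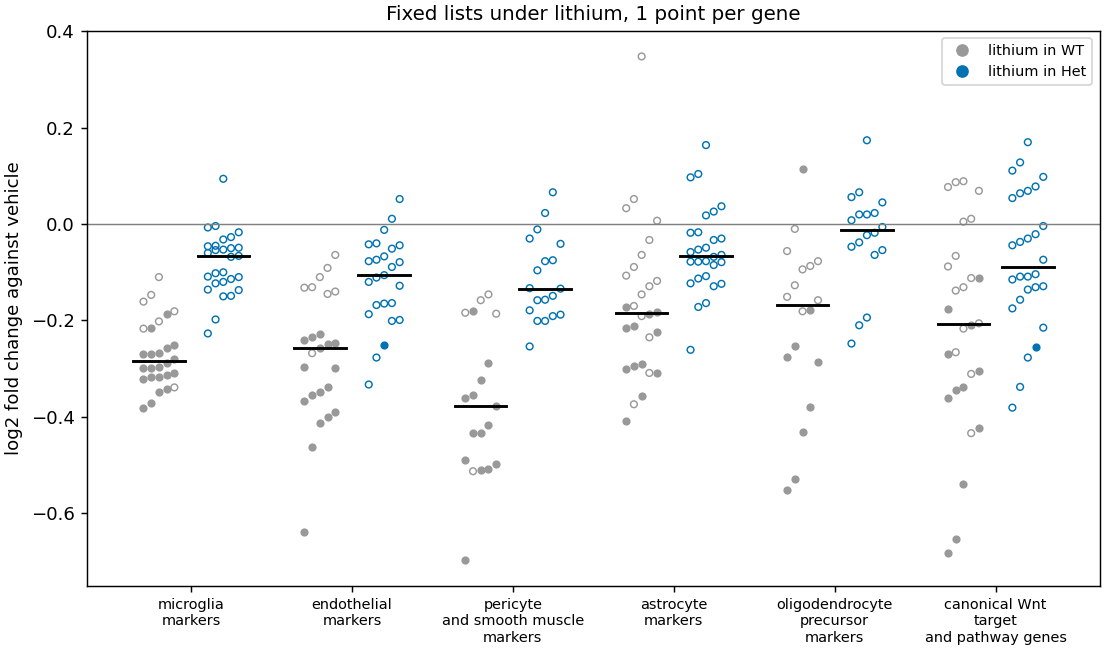
Log2 fold change of lithium against vehicle for each measured gene of 6 lists (points) in WT (grey) and Het (blue) mice. Filled points are genes with an adjusted p below 0.05, and black lines are list medians, which for microglia markers are -0.28 in WT and -0.07 in Het.

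Potassium channel, immediate-early, cholesterol synthesis, ribosomal, heat shock and glucocorticoid-responsive genes were also among the calls in WT lithium. Kcnk9 rose by 0.42 (SE 0.046, adjusted p = 9.15e-09), from 5358.1 ± 406.5 to 7202.6 ± 852.5, and of 30 voltage-gated potassium channel genes 7 rose and 1 fell (adjusted p = 0.0125, and adjusted p = 0.512 with an estimated correlation), with Kcna1 (0.42), Kcnma1 (0.24) and Kcna2 (0.16). Of 32 immediate-early genes 11 fell (adjusted p = 7.78e-06, and adjusted p = 0.31 with an estimated correlation), with Arc (-1.03), Klf10 (-0.55), Klf2 (-0.48) and Sik1 (-0.43). Of 25 cholesterol synthesis genes 10 fell (adjusted p = 0.000116, and adjusted p = 0.285 with an estimated correlation), with Pmvk (-0.31), Mvd (-0.26) and Idi1 (-0.27). Of 78 ribosomal protein genes 29 fell (adjusted p = 7.57e-11, and adjusted p = 0.441 with an estimated correlation), with Rps3 (-0.21), Rpl4 (-0.13), Rps9 (-0.24) and Rps6 (-0.18), the last at adjusted p = 0.184 after GC correction. Of 30 heat shock genes 10 fell (adjusted p = 0.00209, and adjusted p = 0.492 with an estimated correlation), with Xbp1 (-0.25), Hspa8 (-0.17), Creld2 (-0.30) and Hspa1a (-0.41), the last kept in 17 of 20 fits with 1 library left out. Of 24 glucocorticoid-responsive genes 8 rose and 1 fell (adjusted p = 0.0146, and adjusted p = 0.591 with an estimated correlation), with Zbtb16 (0.47), Fkbp5 (0.47), Hif3a (0.68) and Pla2g3 (0.45), and that list was at adjusted p = 0.592 without the 3 libraries with the largest residuals. Adjusted over the lists alone, 9 potassium channel genes were higher and 1 lower, 16 immediate-early genes lower and 1 higher, 11 cholesterol genes lower and 1 higher, 35 ribosomal and 11 heat shock genes lower, and 9 glucocorticoid-responsive genes higher and 1 lower.

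Near the threshold in WT lithium were chromatin regulators (9 of 48 higher and 2 lower, adjusted p = 0.0246). So were autism risk genes (18 of 92 higher and 7 lower, adjusted p = 0.0439). AMPA and kainate receptor genes (2 of 22 higher and 1 lower) were at adjusted p = 0.0423. Mitochondrially encoded transcripts (2 of 13 lower) were at adjusted p = 0.0231. With an estimated correlation these lists were at adjusted p = 0.591, 0.562, 0.24 and 0.591. Tet2 (0.32), Chd2 (0.19), Chd8 (0.12) and Setd1a (0.14) led the first, Mbd5 (0.21) and Cacna1e (0.24) the second beside Chd2 and Chd8, and the receptor auxiliary genes Shisa7 (0.21) and Shisa6 (0.54) the third. Adjusted over the list alone the counts were 9 higher and 2 lower, 22 and 8, 6 and 2, and 1 lower. With the library term the lists were at adjusted p = 0.0806, 0.0597, 0.0597 and 0.0765, and their calls held in 14, 9, 13 and 17 of 20 fits with 1 library left out. The mitochondrial genes that fell were mt-Co2 (-0.80) and mt-Atp6 (-0.94), the latter kept in 5 of 20 fits and not called by edgeR (adjusted p = 0.0737). Without the 3 libraries with the largest residuals mt-Atp6 was at -0.49 (adjusted p = 0.338).

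Of the remaining leading genes in WT lithium, Ralgapa2 (0.45), Ntrk3 (0.31), Zkscan2 (0.53), Iqgap2 (0.56), Rbm33 (0.23), Gmeb1 (0.30), Slc25a27 (0.24) and Nav2 (0.34) rose, and Pnck (-0.48), Hopx (-0.49), Stk40 (-0.35), Nol4l (-0.24), Thbs1 (-0.93), Mob3a (-0.41), Tnfrsf25 (-0.82) and Tmem252 (-1.11) fell. Grin2a rose by 0.29 (adjusted p = 0.0042) and Grin2b by 0.19 (adjusted p = 0.0329). Grin2b kept its call in 13 of 20 fits with 1 library left out. It lost the call with the 4 groups fitted alone (adjusted p = 0.126) and after GC correction (adjusted p = 0.0512). In all 3420 genes were called, 1663 higher and 1757 lower, and 3375 by edgeR. With the 4 groups fitted alone there were 1278. The folds correlated with GC content at -0.317, and 2815 of the calls were made in the same direction after GC correction.

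In Het mice lithium lowered Ctnnb1 as well. It fell by 0.26 on the log2 scale (SE 0.031, adjusted p = 5.4e-07), from 17976.6 ± 646.2 to 15069.9 ± 641.9, in 10 of 10 libraries. The ciliary gene Ahi1 (-0.28), the lactate transporter gene Slc16a1 (-0.38), Tnfrsf25 (-0.70), Stk40 (-0.27), Dnase1l2 (-0.48), Taf15 (-0.16), Klf10 (-0.46), Ppp1r21 (-0.15) and Mirg (-0.27) fell as well. The mitochondrial carrier gene Ucp2 (0.28), Ky (0.45), Gpr157 (0.49), Zfp459 (0.72), Sgpp2 (0.48), Thtpa (0.20), Map10 (0.41), the linker histone gene H1f0 (0.20), Lcmt2 (0.32) and Csmd3 (0.25) rose. Grin2b was at 0.065 (adjusted p = 0.709), Grin1 at -0.025 (adjusted p = 0.925) and Grin2a at 0.14 (adjusted p = 0.412).

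This contrast gave 175 calls, 86 higher and 89 lower, with 169 by edgeR, 553 after GC correction and 496 without the 3 libraries with the largest residuals. Leaving out a Het lithium library gave 54 calls (female replicate 2), 71 (female 3), 106 (male 1), 90 (male 2) or 93 (male 4), and leaving out a Het vehicle library 106 (female 2), 74 (female 3), 98 (male 2) or 75 (male 3). Of the calls 59 of 86 were also higher in WT lithium and 62 of 89 also lower, where independent lists would share 8.03 and 8.78. These contrasts share no library. Their folds correlated at 0.283 across genes, which are not independent replicates, against a range of -0.273 to 0.269 in 1000 simulations of unchanged groups.

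Camera called 14 lists in Het lithium, of which 7 had a called member. With an estimated correlation none of the 14 held, at adjusted p = 0.115 for AMPA receptors and 0.561 to 0.898 for the others. Of the glucocorticoid-responsive genes 4 of 24 rose (adjusted p = 0.000152, 7 over the list alone): Zbtb16 (0.34), and Map3k6 (0.43), Hif3a (0.40) and Fkbp5 (0.33), of which the last 3 kept their calls in 19, 19 and 16 of 20 fits with 1 library left out. Map3k6 (adjusted p = 0.0539) and Hif3a (adjusted p = 0.0551) lost theirs without Het lithium female replicate 2. Of 30 potassium channel genes 2 rose (adjusted p = 0.000469, 6 over the list alone), Kcnn2 (0.19) and Kcns2 (0.21), kept in 16 and 14 fits. Of 78 ribosomal protein genes 3 fell (adjusted p = 1.39e-14, 10 over the list alone), Rpl30 (-0.20), Rps23 (-0.16) and Rpl17 (-0.19), kept in 4, 6 and 4 fits. In each of 4 lists 1 member fell. These were Ctnnb1 of 28 Wnt genes (adjusted p = 0.00577), Tek (-0.25) of 25 endothelial markers (adjusted p = 3.36e-05) and Irf9 (-0.28) of 28 interferon genes (adjusted p = 0.000411), where Tek and Irf9 kept their calls in 5 and 18 fits, and 1 of 25 cholesterol genes (adjusted p = 0.0138). Over the list alone these were 1, 2, 1, and 2 lower with 1 higher.

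No member was called in the other 7 lists. Among those the AMPA receptor (22 measured, adjusted p = 0.00353) and GABA (20, adjusted p = 0.0113) lists ranked high. The oligodendrocyte (34, median -0.25, adjusted p = 7.26e-06), microglia (28, adjusted p = 0.00302), pericyte (19, adjusted p = 0.0113), mitochondrially encoded (13, median -0.17, adjusted p = 0.023) and astrocyte (28, adjusted p = 0.0274) lists ranked low. With 1 library left out, the astrocyte, mitochondrial and cholesterol calls held in 13, 15 and 17 of 20 fits, and those for GABA, microglia and pericytes in 19.

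Between genotypes under lithium 5 genes were called, each at an adjusted p of 0.0456 and in 10 of 10 libraries. Neurl1b (0.28, SE 0.058), Tnfrsf25 (0.58, SE 0.12) and the vesicle release gene Rims4 (0.21, SE 0.044) were higher in Het mice, and the mucin gene Muc1 (-0.84, SE 0.172) was among the 2 that were lower. Grin2b was at -0.031 (adjusted p = 0.887), Grin1 at 0.028 (adjusted p = 0.914) and Grin2a at -0.071 (adjusted p = 0.746). At an unadjusted p of 0.05 there were 2031 genes, or 2038 by edgeR, which called 6. Limma called 0 after GC correction, 0 with the Rps6-ps4 term, 0 without the 3 libraries with the largest residuals and 0 with the 4 groups fitted alone. With the Rps6-ps4 term the folds of the genes named changed little, at 0.275, 0.57, 0.22 and -0.82 (adjusted p = 0.0737 for each). Leaving out a Het lithium library gave 0 calls (female replicate 1), 3 (female 2), 2 (female 4), 2 (female 5), 1 (male 1), 0 (male 2), 0 (male 3), 8 (male 4) or 1 (male 5). Leaving out a WT lithium library gave 81 (female 1), 77 (female 2), or 0 (females 3, 4 and 5 and males 2, 3 and 5).

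Within a sex, Ctnnb1 fell with lithium in all 4 groups, by 0.31 on the log2 scale in WT females, 0.38 in WT males, 0.24 in Het females and 0.27 in Het males (adjusted p = 3.23e-05, 8.42e-08, 0.0143 and 0.00162), although in Het females the call held in 8 of 10 fits with 1 library left out. With the groups compared fitted alone its calls ended at unchanged folds in WT females (adjusted p = 0.0904) and Het females (adjusted p = 0.306). In males, Het mice had more Meg3 (0.43), Miat (0.47) and Kcnk9 (0.37) in vehicle and less Fam89a (-1.62, kept in 2 of 10 fits and not called by edgeR, adjusted p = 0.0793). Fluoxetine raised Tmem82 (1.24), Ucp2 (0.52) and Atp10d (0.73) and lowered Bcor (-0.49), Nol4l (-0.34) and Nr4a3 (-0.96) in WT females, and raised Spaca6 (0.53), Rbm33 (0.29) and Rad52 (0.36) and lowered Fam53b (-0.77), Nol4l (-0.35) and Banp (-0.58) in WT males. In Het females it raised Mmp16 (0.58), Exph5 (0.78) and Zc3h6 (0.71) and lowered Mirg (-0.69), Rpl31-ps8 (-0.75) and Tnfrsf25 (-1.47), and in Het males it raised Atp10d (0.88), Zc3h6 (0.69) and Plin4 (1.71) and lowered Nol4l (-0.47), Fam129b (-0.78) and Bcor (-0.63). Zc3h6 lost its call with the library term in Het females (0.56, SE 0.157 against 0.098 without the term, adjusted p = 0.115) and males (0.57, SE 0.138 against 0.098, adjusted p = 0.0651), where its fold held at least 75% of its size. Rpl31-ps8 lost its call in Het females at a smaller fold (-0.29, adjusted p = 0.297). Lithium raised Sfswap (0.28), Slc35f6 (0.42) and Wipf3 (0.62) and lowered Nol4l (-0.34) and Gid4 (-0.41) in WT females, and raised Nvl (0.46), Ntrk3 (0.37) and Kcnk9 (0.42) and lowered Pmvk (-0.46) and Taldo1 (-0.32) in WT males.

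The genotype contrast in vehicle gave 0 calls in females by limma (671 at an unadjusted p of 0.05) and 0 by edgeR (663), and 21 in males, 20 higher and 1 lower. The male count was 4, 5 or 11 without Het vehicle male replicates 1, 3 or 4, 7, 5, 6 or 10 without WT vehicle male replicates 1 to 4, and 42 without WT vehicle male replicate 5. It was 97 after GC correction, 102 without the 3 libraries with the largest residuals and 0 with the groups fitted alone. Fluoxetine in Het mice gave 4483 calls in females and 2818 in males, 35 and 29 with the library term, 143 and 141 with the Rps6-ps4 term, 2581 and 1100 after GC correction and 5785 and 4520 without the 3 libraries. Without Het vehicle female replicate 3 the female count was 2724, and without Het fluoxetine male replicate 3 or Het vehicle male replicate 2 the male count was 1652 or 1686. Of these calls 640 higher and 1054 lower genes were shared by the sexes, where independent lists would share 147 and 208. Fluoxetine in WT mice gave 388 calls in females and 380 in males, with 60 higher and 53 lower genes shared (2.51 and 1.64 for independent lists). The female count was 221 and 226 without WT fluoxetine female replicates 2 and 4, 251 and 206 without WT vehicle female replicates 1 and 4, 604 after GC correction and 122 with the groups fitted alone. The male count was 241, 183 and 213 without WT fluoxetine male replicates 1, 3 and 4, 179, 241 and 172 without WT vehicle male replicates 1 to 3, 634 after GC correction and 696 without the 3 libraries.

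Lithium in Het mice gave 2 calls in females and 1 in males, 15 and 24 after GC correction, 34 and 42 without the 3 libraries, and 0 by limma (1762 at an unadjusted p of 0.05) and 8 with the groups fitted alone. The female count was 15, 1, 0 and 1 without Het lithium female replicates 1, 2, 3 and 5, and 1, 0 and 16 without Het vehicle female replicates 1, 3 and 4, and the male count was 2 without Het lithium male replicate 1. Lithium in WT mice gave 2095 calls in females and 3704 in males, with 183 higher and 204 lower genes shared (113 and 105 for independent lists). Without WT lithium female replicate 3 or 5 the female count was 1150 or 668, and without WT lithium male replicate 5 the male count was 584. The counts were 2860 and 1150 after GC correction (the correlation of folds with GC content was -0.665 in males), 805 and 1190 without the 3 libraries, and 3 and 8 with the groups fitted alone.

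The interaction of genotype with fluoxetine was called for 4272 genes, 2128 higher and 2144 lower, 1373 after GC correction, 42 with the Rps6-ps4 term and 8 with the library term. Of the 6 genes named here 2 kept their calls with the Rps6-ps4 term and 0 by limma with the library term. With the library term 3 of them held at least 75% of their fold and ended as the SE rose, Mapk1ip1 at -0.34 (SE 0.079, against 0.049 without the term), Sfswap at -0.25 (SE 0.065, against 0.041) and Kitl at 0.33 (SE 0.121, against 0.076), and the other 3 held 50% or less. Kitl was at 0.43 with the Rps6-ps4 term (adjusted p = 0.0627). Kitl (0.44) and Nexmif (0.43) had the higher fold in Het mice, as did Zfp37 (0.38, at adjusted p = 0.0712 after GC correction), and Rpl31-ps8 (-0.71), Mapk1ip1 (-0.38) and Sfswap (-0.32) the lower. The interaction of genotype with lithium was called for 12 genes, 1 higher and 11 lower, for 32 after GC correction, 32 with the library term, 21 without the 3 libraries, 7 after rescaling and 6 with the groups fitted alone. Meg3 (-0.34, SE 0.062, adjusted p = 0.00609), Kcnk9 (-0.38, SE 0.065, adjusted p = 0.00402) and Ankrd16 (-0.45, SE 0.081, adjusted p = 0.00609) rose less or fell more with lithium in Het than in WT mice, and Rcn3 (0.69) was kept in 13 of 40 fits with 1 library left out and not called by edgeR (adjusted p = 0.0654). With 1 library left out this count was 7, 7 and 21 without Het lithium female 2, male 2 and male 4, 7 and 7 without Het vehicle males 1 and 2, 47, 53, 6 and 7 without WT lithium females 1, 2, 3 and 5, 22 and 22 without WT lithium males 1 and 4, 5, 59, 40 and 7 without WT vehicle females 1, 2, 3 and 5, and 6, 7 and 31 without WT vehicle males 1, 3 and 5.

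The interaction of sex with lithium in WT mice was called for 1716 genes, 860 with a higher and 856 with a lower fold in males than in females, and for 1881 by edgeR. Zfp933 (0.87, adjusted p = 0.000544), Senp8 (0.85) and the splicing factor gene Tra2a (0.66) had the higher fold in males, and Msto1 (-0.53), the elongation factor gene Nelfcd (-0.44) and the initiation factor gene Gtf2f1 (-0.50) the lower, the last 5 each at an adjusted p of 0.0138. All but Zfp933 kept their calls in 17 of 20 fits with 1 library left out. Without the 3 libraries limma called 1 gene, with Zfp933 at 0.62 (adjusted p = 0.0477), Senp8 at 0.62, Tra2a at 0.40, Msto1 at -0.32, Nelfcd at -0.27 and Gtf2f1 at -0.28, the last 5 at adjusted p = 0.635 to 0.688. The count was 1 without WT lithium female replicate 5, WT lithium male replicate 5 or WT vehicle female replicate 2, 3276 without WT lithium female replicate 4, and 916, 999 and 825 without WT vehicle male replicates 2, 3 and 4. It was 69 after GC correction, 280 with the library term, 22 with the Rps6-ps4 term and 0 with the groups fitted alone. Limma called 0 genes for the interaction of sex with genotype in vehicle (469 at an unadjusted p of 0.05, 460 by edgeR), with fluoxetine in Het (1225 and 1168) and WT mice (703 and 729) and with lithium in Het mice (416 and 413), and edgeR called 0 in each. Without Het fluoxetine female replicate 1 the count for fluoxetine in Het mice was 3.

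Whether drug effects in Het mice oppose the genotype difference was read from correlations of folds across genes. Comparisons with vehicle in Het mice share the Het vehicle libraries with the genotype contrast, which alone gives a negative value. Genotype and fluoxetine in Het mice had a covariance of -0.019, against -0.0143 in simulated unchanged groups (difference -0.00471), and correlated at -0.323 (simulated mean -0.499, range -0.682 to -0.281). Genotype and lithium in Het mice had a covariance of -0.0131 (simulated -0.0143, difference 0.00111) and correlated at -0.358 (simulated mean -0.498, range -0.685 to -0.302). With the vehicle libraries split between the contrasts the means over 200 splits were -0.0825 and -0.00624, inside the simulated ranges of -0.262 to 0.252 and -0.261 to 0.246. The ranges given for split libraries were simulated for 1 fixed split. A mean over 200 splits varies less, so they are wide for it. Of the 92 genes higher in Het vehicle mice, 50 were lower with fluoxetine in Het and 4 lower with lithium in Het, overlaps that the shared Het vehicle libraries also favour. In WT mice, folds of fluoxetine and lithium correlated at 0.603 (simulated 0.499), with a covariance of 0.0311 (simulated 0.0142), and at 0.255 with the vehicle libraries split (simulated range -0.237 to 0.265). They shared 411 higher and 331 lower genes, and as both use the WT vehicle libraries, unchanged groups would share some too.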

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

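The tests on GC-corrected splits, on calls lost after GC correction, on the set with no Rps6-ps4 read and on leaving out 2 lithium libraries were written before their results were seen; the tests on pseudogenes, on the fold of all calls after GC correction, on the set with the lowest pseudogene level, on kept calls, on 1 lithium library and on shared vehicle libraries, the spread between libraries and the bound for splits of uncorrected values were chosen after.

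Single libraries lay far from the other 4 of their group on measures of the library. Total reads, in megareads, were 36.84 in Het fluoxetine female replicate 1 and 24.14 in Het lithium female replicate 1. WT lithium male replicate 5 had reads in 17801 genes. The top gene took 3.8% of reads in WT fluoxetine female replicate 5, 2.56% in WT lithium female replicate 4, 3.16% in WT lithium male replicate 5 and 3.63% in WT vehicle male replicate 1. Chance alone sets apart a library in about 5% of groups.

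Among the 236 named genes, a library stood apart in 211 of 2832 group tests, or 7.45%, where chance gives about 5%. The numbers of genes were 37 for WT lithium male replicate 5 and 20 for WT vehicle female replicate 2. For Het vehicle female they were 1 (replicate 2) and 14 (replicate 3), and for Het vehicle males 1 to 5 they were 1, 1, 1, 2 and 4. For Het fluoxetine females 1 to 5 they were 6, 3, 2, 4 and 2, and for Het fluoxetine males 7 (replicate 1), 6 (replicate 2) and 3 (replicate 5). For Het lithium females 1 to 5 they were 2, 1, 1, 1 and 1, and for Het lithium males 4 (replicate 1), 6 (replicate 4) and 3 (replicate 5). For WT fluoxetine females 1 to 5 they were 2, 4, 3, 2 and 11, and for WT fluoxetine males 3 (replicate 2), 1 (replicate 3), 11 (replicate 4) and 1 (replicate 5). For WT lithium females they were 2 (replicate 1), 1 (replicate 3), 3 (replicate 4) and 10 (replicate 5), and for WT lithium males 1 to 4 they were 2, 2, 1 and 1. WT vehicle females 3 and 4 had 3 and 1, and WT vehicle males 1, 4 and 5 had 6, 5 and 3.

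Genes were called for 3 interactions. The interaction of genotype with fluoxetine was called for 4272 genes (42 with the Rps6-ps4 term and 8 with the library term), with Zfp37 (0.38), Kitl (0.44), Nexmif (0.43), Rpl31-ps8 (-0.71), Mapk1ip1 (-0.38) and Sfswap (-0.32) in the lead, and that with lithium for 12, with Rcn3 (0.69), Kcnk9 (-0.38), Ankrd16 (-0.45) and Meg3 (-0.34). The interaction of sex with lithium in WT mice was called for 1716 genes (1 without WT lithium male replicate 5), with Zfp933 (0.87), Senp8 (0.85), Tra2a (0.66), Msto1 (-0.53), Nelfcd (-0.44) and Gtf2f1 (-0.50). In 100 splits, 1 called as many genes as the real 4272 (highest other 2036), 3 as many as the real 12 (highest other 564) and 6 as many as the real 1716 (highest other 3047), so chance is not excluded for the last. Splits that mix groups unevenly can show a drug or genotype difference as an interaction, so the 6 of 100 decides nothing on chance.

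The first pattern weighed is the genotype difference under fluoxetine. After GC correction 1537 calls were kept, and no other split of corrected values called over 720. Splits mix the libraries that share a GC trend, so a GC bias left by the correction is not excluded as a cause of the kept calls. Over all 7042 calls the median log2 fold fell from 0.22 (SE 0.0565) to 0.07 (SE 0.0442), 31.7% of its size, so a GC trend may account for part of it, while the 22.2% for the 5505 lost calls decides nothing, as a call was lost only below a median of 65.6% of its first fold. Reads shared with pseudogenes may account for 16 of the 23 calls over 4-fold but not for all calls, of which 76 were pseudogenes. A batch and a response that depends on genotype cannot be told apart for the kept calls (that 9 of 10 Het fluoxetine libraries lay below every other library on these pseudogenes decides nothing, as they were chosen as low in that group), since the result depends on a few libraries: a term for the 11 libraries with no Rps6-ps4 read left 75.5% of the median fold of kept calls (jackknife SE 22.6, range 55.8% without WT lithium male replicate 1 to 93.7% without WT vehicle female replicate 2, so the bound of 75% set beforehand was not passed by more than the spread), and the later term for the 10 libraries with the lowest level left 55.8% (SE 25.2, range 31.7% without Het fluoxetine male replicate 1 to 75.7% without WT vehicle female replicate 2), and 31.8% for all calls.

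The second pattern is the interaction of sex with lithium in WT mice. Without WT lithium male replicate 5 limma called 1 gene, and the median log2 fold of the called genes was 77.7% of its size with it. Without that library and WT lithium female replicate 5 it was 63%. A sex difference, an effect of these libraries and a GC trend cannot be told apart. The fold was neither kept nor lost, and each arm holds 5 libraries. Folds correlated with GC content at -0.687, with 69 calls after GC correction.

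The third pattern is the negative correlation of drug effects in Het mice with the genotype difference. With the Het vehicle libraries split between the contrasts the mean r was -0.0825 for fluoxetine (simulated range -0.262 to 0.252) and -0.00624 for lithium (-0.261 to 0.246). Shared vehicle libraries may therefore account for the negative values of -0.323 and -0.358. A reversal of the genotype difference too small for these ranges stays open.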

How the results depend on the processing

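The fits by edgeR, after GC correction, without 3 libraries, with the library term and with the Rps6-ps4 term were chosen after seeing the data. DESeq2 was not run, as the values are normalised. Direction changes of genes called under neither setting were not counted as reversals, and except where stated the causes were not tested.

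With the library term calls were 7 (genotype in fluoxetine), 49 (fluoxetine in Het), 35 and 29 (fluoxetine in Het females and males), 8 and 32 (genotype by fluoxetine and by lithium), 1 (genotype in vehicle, female), 1 (sex by fluoxetine in Het) and 280 (sex by lithium in WT), and 11 lists were called for fluoxetine in Het. Grin2a and Hist2h2aa2 reversed for genotype in fluoxetine, at -0.012 and 0.63, neither called. With the Rps6-ps4 term, the set tried first, calls were 15, 0 (genotype in lithium), 332, 143 and 141, 42 and 22 (sex by lithium in WT), with 11 lists for fluoxetine in Het. Both terms raise the SE of these contrasts.

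After GC correction calls were 210 (genotype in vehicle), 2203 (genotype in fluoxetine), 0 (genotype in lithium), 3868 (fluoxetine in Het), 553 (lithium in Het), 2581, 604 and 15 in females (fluoxetine in Het, fluoxetine in WT, lithium in Het), 97, 1100, 634, 24 and 1150 in males (genotype in vehicle, fluoxetine in Het, fluoxetine in WT, lithium in Het, lithium in WT), 1373 and 32 (genotype by fluoxetine and by lithium) and 69 (sex by lithium in WT), with 11 lists for fluoxetine in Het. Without the 3 libraries calls were 343 (genotype in vehicle), 0 (genotype in lithium), 496 (lithium in Het), 34 and 805 in females (lithium in Het and WT), 102, 4520, 696, 42 and 1190 in males (the 5 contrasts in the order above), 21 (genotype by lithium) and 1 (sex by lithium in WT), and the r of fluoxetine in Het with fluoxetine in WT was 0.178.

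With the groups compared fitted alone, which leaves fewer libraries to estimate the spread, calls were 47 (genotype in vehicle), 0 (genotype in lithium), 1278 (lithium in WT), 122, 0 and 3 in females (fluoxetine in WT, lithium in Het, lithium in WT), 0, 8 and 8 in males (genotype in vehicle, lithium in Het, lithium in WT), 6 (genotype by lithium), 1 (sex by fluoxetine in Het) and 0 (sex by lithium in WT). Lithium in Het females gave 1 call with a pseudocount of 5, with the replicate block and by edgeR, and genotype by lithium gave 7 after rescaling. With an estimated correlation camera called 0 lists (genotype in vehicle, fluoxetine in Het, lithium in Het, lithium in WT) and 1 (fluoxetine in WT), and fry called 0 for genotype in vehicle, 12 for fluoxetine in Het and 1 for lithium in Het. With vehicle libraries split, r was -0.0825 and -0.00624 (genotype against fluoxetine and lithium in Het), 0.142 and 0.255 (fluoxetine against lithium in Het and WT), and 0.105 and 0.138 (genotype against fluoxetine and lithium in WT, pairs added after seeing the data).

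Leaving out 1 library at a time gave 17 to 132 calls (genotype in vehicle), 6503 to 7166 (genotype in fluoxetine), 0 to 81 (genotype in lithium), 6245 to 7036 (fluoxetine in Het), 1215 to 1593 (fluoxetine in WT), 54 to 259 (lithium in Het) and 2650 to 4296 (lithium in WT). In females the ranges were 0 to 0, 2724 to 4713, 206 to 351, 0 to 16 and 668 to 2529 (genotype in vehicle, fluoxetine in Het and WT, lithium in Het and WT), and in males 4 to 42, 1652 to 3173, 172 to 377, 1 to 2 and 584 to 4320. Interactions ranged from 3279 to 4551 (genotype by fluoxetine), 5 to 59 (genotype by lithium), 0 to 3 (sex by fluoxetine in Het) and 1 to 3276 (sex by lithium in WT), and the other sex interactions from 0 to 0. Lists called ranged from 9 to 17 (genotype in vehicle), 7 to 10 (fluoxetine in Het), 9 to 18 (lithium in Het), 8 to 15 (fluoxetine in WT) and 16 to 22 (lithium in WT), and the log2 fold of Grin2b in vehicle from 0.065 to 0.127.

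Of 341 values for genes that the naming rule selects, calls ended with the direction kept for 73 with the library term, 51 with the Rps6-ps4 term, 55 with the groups fitted alone, 16 after GC correction, 11 without the 3 libraries, 7 by edgeR, 4 with the replicate block, 2 after rescaling, 1 with a pseudocount of 5 and 0 without the filter on low values. A further 2 with the library term and 1 after GC correction lost their calls and did not keep their direction. With 1 library left out 387 tests of named genes lost a call, 6212 did not change and 1 gained one. The replicate number does not pair libraries: same-number libraries correlated at a median r of -0.0069.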

Other observations

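The tests on GC-corrected splits were written before their results were seen, and the bound of 5 in 100 for the splits of uncorrected values after. The vehicle-sharing comparison with WT drug effects was chosen after seeing the data.

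Genes raised in Het vehicle mice overlapped with genes that both drugs raised in WT mice. Of the 92 higher genes, 44 were higher with fluoxetine in WT and 44 with lithium in WT. These contrasts share the WT vehicle libraries, which alone gives a positive correlation: r was 0.469 and 0.484, against 0.5 and 0.498 in simulations, and 0.105 and 0.138 with the vehicle libraries split. Rbm33, Spaca6 and Kcnk9 are among the named genes that rose in 2 or more of these contrasts. In Het mice fluoxetine and lithium shared 61 higher and 65 lower genes, but these contrasts share the Het vehicle libraries. Their r of 0.412 lay below the simulated mean of 0.496 for unchanged groups (range 0.274 to 0.671). Their covariance of 0.0231 lay above that of 0.0141 (0.00683 to 0.025). The contrasts of fluoxetine in Het and WT mice, which share no library, shared 280 higher and 343 lower (148 and 145) with an r of 0.108 (simulated range -0.253 to 0.248).

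In 100 splits of the libraries, the real one included, 1 gave as many calls as the real count for genotype in vehicle (105, highest other 3), genotype in fluoxetine (7042, 2689), fluoxetine in Het (6952, 860), fluoxetine in WT (1502, 309), lithium in Het (175, 1) and lithium in WT (3420, 2968). So a chance placement of single libraries can be excluded for these counts by that bound. Chance differences between litters cannot, as the labels do not name litters and the splits move single libraries. For genotype in lithium it was 2 (5, 10), and as the count was 0 under 4 alternatives, little rests on it. In females the number of splits was 1 for fluoxetine in Het (4483, 1783), fluoxetine in WT (388, 9) and lithium in WT (2095, 917), 2 for lithium in Het (2, 9) and 100 for genotype in vehicle (0, 1). In males it was 1 for fluoxetine in Het (2818, 745), fluoxetine in WT (380, 5), lithium in Het (1, 0) and lithium in WT (3704, 1267), and 2 for genotype in vehicle (21, 62). After GC correction it was 1 for genotype in fluoxetine (2203, 720) and 1 for genotype by fluoxetine (1373, 24). Among sex interactions it was 100 for genotype (0, 188), fluoxetine in Het (0, 3430), fluoxetine in WT (0, 148) and lithium in Het (0, 1). For these interactions split counts up to 3430 can hold a drug or genotype difference and do not measure chance alone.

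For the number of lists called, splits were 61 for genotype in vehicle (11, highest other 23), 95 for fluoxetine in Het (7, 24), 70 for fluoxetine in WT (10, 22), 45 for lithium in Het (14, 24) and 3 for lithium in WT (20, 24). Chance is not excluded for the number of lists in the first 4 contrasts. The median count of the other splits was 12, 12, 12, 13 and 11. For single lists, the number of splits with a p as small under fluoxetine in WT was 1 (heat shock), 2 (cholesterol, immediate-early), 3 (Wnt), 4 (glucocorticoid), 12 (endothelial), 13 (interferon), 30 (pericyte), 47 (astrocyte) and 50 (mitochondrially encoded). Under lithium in WT it was 1 (microglia, endothelial, pericyte, astrocyte), 2 (Wnt, oligodendrocyte precursor), 3 (AMPA), 4 (interferon), 7 (matrix), 12 (cholesterol), 13 (meningeal, immediate-early), 14 (oligodendrocyte), 18 (potassium channel), 24 (heat shock), 31 (ribosomal), 32 (mitochondrially encoded), 35 (autism risk), 39 (chromatin) and 48 (glucocorticoid). Under fluoxetine in Het it was 4 (GABA), 5 (ribosomal, oxidative phosphorylation), 6 (immediate-early), 7 (glucocorticoid), 10 (cholesterol) and 29 (endothelial). Under lithium in Het it was 2 (glucocorticoid), 3 (AMPA), 9 (ribosomal), 14 (Wnt, potassium channel), 15 (GABA), 24 (endothelial), 29 (cholesterol, pericyte), 32 (oligodendrocyte), 33 (interferon), 45 (mitochondrially encoded), 47 (microglia) and 55 (astrocyte). For genotype in vehicle it was 8 (oligodendrocyte precursor), 10 (meningeal), 13 (cholesterol), 19 (pericyte), 22 (matrix), 23 (oligodendrocyte, immature neuron), 31 (astrocyte), 51 (chromatin), 61 (microglia) and 66 (oxidative phosphorylation).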
